A study of Morus alba var. atropurpurea with 12 samples.

How the data were processed

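Seedlings of the mulberry cultivar Yuesang10 were grown in soil for 3 months, trimmed to shoots of 10 cm and roots of 2 cm, and moved to Hoagland nutrient solution, per the labels' protocols. After 3 days cadmium chloride was added for 20 days, the solution being changed every 5 days. RNA was extracted from roots for sequencing. The labels of the treatment speak of 6 groups, but they name only 5, 10 and 20 mM beside the control, and the 12 samples used here fall into those 4 groups of 3. The unit mM is the one the labels give and could not be checked against the values. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

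The authors deposited 1 table per library with FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each transcript, per the file headers. The aligner, counting tool, genome build and filters are not given in the sources used here. The tables list only values above 0, to 2 decimals with a lowest value of 0.01, and transcripts not listed were set to 0. FPKM already divides out library size and transcript length, so a change in a few abundant transcripts can shift all others. Transcript identifiers were used as the tables give them, and these do not pair them with gene names. Lists of gene families and pathways had been fixed as patterns in product descriptions, and neither these lists nor the camera test over them could be applied without names. Near-identical transcripts that share reads could not be identified.

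Read depth was examined from low values. In 667 sparse transcripts (listed in 4 to 9 libraries, lowest value at least 0.3 FPKM), 94.4% of 4247 values lay within 0.1 of a whole multiple of the worth of 1 read, and among the 1565 values above 1.5 times that worth 90.2% did. The relative worth of 1 read, which falls as depth rises, ran from 0.945 to 1.06. Its group means were 1.06 ± 0.0116 for control, 0.992 ± 0.0260 at 5 mM, 0.970 ± 0.0305 at 10 mM and 0.985 ± 0.0185 at 20 mM (SD, n = 3). Absolute depth stays unknown, so no counting interval is given.

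Values were analysed as log2(FPKM + 1), and changes on that scale understate those of low transcripts. Of 22727 transcripts listed in any library, the 17782 with at least 1 FPKM in at least 3 libraries were tested and 4945 were left out. Group means were fitted over all 12 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no block. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05. All adjusted p-values are two-sided values from limma. The same fit gave the 3 doses against control, the 3 differences between doses and a moderated F test over the doses against control. The share of changed transcripts was estimated from the unadjusted p-values with the convex decreasing density method of limma. This method takes the p-values of unchanged transcripts as uniform. A second limma fit used the dose in mM as a linear covariate. At most 2 transcripts per direction are named in each comparison. They had the largest log2 change among called transcripts with a mean of at least 5 FPKM in 1 of the groups and no overlap between groups. This is the part of the naming rule set for identifiers without names.

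The replicate numbers were checked for pairing through correlations, across transcripts, of deviations from group means. For control and 10 mM, all 3 same-numbered pairs exceeded 0.1 (0.268, 0.170 and 0.176), so the blocked value is given beside that comparison. The labels name no shared batch or day. In no other pair of groups did all 3 exceed 0.1.

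Shared controls were modelled in 100 simulations in which the residuals of the 12 libraries, scaled up for the fitted means, were shuffled between libraries around common means. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median scaling, quantile normalization, no variance trend with robust moderation, array weights, the replicate block, fits of only the 2 groups compared, a minimum absolute log2 change of 1, other forms of the dose trend, and each library left out in turn. Median scaling moved the median log2 change of all transcripts from 0.09 to -0.03 at 10 mM, a shift of over 0.1, and from 0.06 to -0.02 at 20 mM.

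The procedure was tested on simulated data, with normal noise drawn independently for each transcript and library. Spread shared by transcripts within a library was left out, so false calls in the real data can be more frequent. The simulations from shuffled residuals, which keep that spread, reached 36 calls at 10 mM against control. For 20 mM against control, over 17453 transcripts, it recovered 22% of transcripts changed by 1 log2 unit, 76% of those changed by 2 and 86% of those changed by 4, with 4 calls among unchanged transcripts. At a change of 0.5 log2 units it recovered 0%. A simulated 5 mM comparison with no change gave 0 calls with limma. For the linear trend, over 17467 transcripts, it recovered 34.7% at 1, 87.2% at 2 and 91.1% at 4 log2 units, and the F test recovered 20.4%, 68.1% and 91.1%. Changed transcripts that fell below the filter counted as missed for 20 mM against control. They were left out of the percentages for the trend and the F test, so the percentages cannot be compared directly.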

Results

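Messenger RNA was profiled in roots of mulberry (Morus alba var. atropurpurea, cultivar Yuesang10), a woody crop grown for its leaves and fruit, after 20 days in nutrient solution with cadmium chloride. Cadmium is a toxic metal with no known use in the plant. The 4 groups were a control without cadmium and doses of 5, 10 and 20 mM, with 3 libraries in each. The sample labels give root as the tissue, whereas the text describing the series speaks of fruit, and the values are treated here as those of roots. The deposited values are FPKM per transcript, and transcripts are given only as XM identifiers without gene names. Each library listed between 19381 (control replicate 2) and 20071 (5 mM replicate 3) transcripts above 0. A transcript that a file did not list was set to 0. The number of reads per library is unknown, but the steps between low values put the worth of 1 read within a 1.13-fold range over the 12 libraries. The 10 most abundant transcripts held between 5.43% (control replicate 3) and 7.30% (20 mM replicate 3) of a library's FPKM sum. Correlations between 2 libraries across the 17782 tested transcripts, which are not independent replicates, ran from 0.911 to 0.969. Within groups the lowest was 0.924, between replicates 1 and 2 at 10 mM.

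The first comparison asked what the lowest dose did to the root transcriptome. At 5 mM, XM_010098200.1 was present at 68.63, 77.72 and 43.61 FPKM in the 3 treated libraries and was listed in no control library (adjusted p = 0.0387). XM_010110569.1, named after its values were seen because its level lies below the naming limit, was likewise listed in no control and stood at 2.64, 3.05 and 3.06 FPKM at 5 mM (adjusted p = 0.0193). These 2 transcripts were the whole of the called response, and both were higher. No transcript was called lower with limma, against 744 lower and 880 higher at an unadjusted p under 0.05, but a fit of only the control and 5 mM libraries called 1 higher and 3 lower. Over all tested transcripts, 16.9% had no overlap between the 3 treated and 3 control libraries, where chance gives 10% for a single transcript. Transcripts of a library can move together, so this excess is not by itself a response. The split that exchanged control replicate 3 with 5 mM replicate 1 gave 1692 transcripts at an unadjusted p under 0.05, above the 1624 of the real split. The estimated share of changed transcripts, 18.7%, has the same limit. The count of 2 calls was 0 without any 1 of control replicates 1 and 2, 5 mM replicates 1, 2 and 3 or 20 mM replicate 3, and 1 without control replicate 3 or 10 mM replicate 1. In those same 8 fits the adjusted p of XM_010098200.1 lay between 0.0669 and 0.301. Its call was also lost without a filter (0.0654), with a mean of at least 5 FPKM (0.0740), with median scaling (0.0569) or quantile normalization (0.0551), without the variance trend and with robust moderation (0.0659), and with the replicate block (0.139), within 0.000583 to 0.301 over its alternatives.

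At 10 mM, 17 transcripts rose and 6 fell against the control. XM_010110850.1 rose from 10.3 ± 3.21 to 79.0 ± 41.5 FPKM (SD, n = 3), a log2 change of 2.68 ± 0.38 (SE, adjusted p = 0.0395). XM_010100057.1 rose from 13.9 ± 9.03 to 82.2 ± 13.9 FPKM, a log2 change of 2.66 ± 0.39 (adjusted p = 0.0428). XM_010089470.1 fell from 66.6 ± 34.9 to 2.85 ± 1.31 FPKM, a log2 change of -4.05 ± 0.39 (adjusted p = 0.00386). XM_010113721.1 fell from 191 ± 43.2 to 12.1 ± 1.66 FPKM, a log2 change of -3.85 ± 0.61 (adjusted p = 0.0428). The median log2 change was 1.46 among the 17 that rose, 1.45 without 1 transcript that no control library listed, and -2.09 among the 6 that fell. All 23 showed no overlap between the 2 sets of 3 libraries, as did 18.8% of all tested transcripts, where chance gives 10%. The split between directions depended on scaling, with 9 higher and 11 lower after median scaling and 15 and 15 after quantile normalization.

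Replicate 1 at 10 mM stood apart on the first principal component (20.3% of the variance), at -21.1 against 33.2 and 23.9 for replicates 2 and 3, within the range of -51.2 to -13.7 of the control and 5 mM libraries. The 10 mM count of 23 rested on single libraries. It was 2 without control replicate 1, 5 mM replicate 2 or 10 mM replicate 2, 3 without 10 mM replicate 3, 4 without 5 mM replicate 3, 5 without control replicate 2, 6 without 20 mM replicate 1, 10 without 20 mM replicate 3, 15 without 5 mM replicate 1 and 43 without 10 mM replicate 1. The call of XM_010089470.1 held in all 12 fits that left out 1 library and was lost only where control and 10 mM were fitted alone (adjusted p = 0.145, within 0.00192 to 0.145 over its alternatives). The call of XM_010110850.1 was lost without control replicates 1 or 2, 5 mM replicates 2 or 3, 10 mM replicates 2 or 3, or 20 mM replicates 1 or 3, with adjusted p between 0.0515 and 0.132. That of XM_010100057.1 was lost in the same fits, with control replicate 3 in place of control replicate 2, at adjusted p between 0.0542 and 0.134. Both were also lost without a filter (0.0574 each) and without the variance trend and with robust moderation (0.0605 each). Where control and 10 mM were fitted alone their adjusted p was 0.229 and 0.204. Median scaling ended the call of XM_010100057.1 too (0.0510). The call of XM_010113721.1 was lost in 10 of the 12 fits, all but those without 20 mM replicates 1 or 2, at adjusted p between 0.0616 and 0.137. It was also lost without a filter (0.0729) and without the variance trend and with robust moderation (0.0619). Same-numbered control and 10 mM libraries deviated together, and with the replicate number as a block the count was 8, 7 higher and 1 lower, with XM_010113721.1 no longer called, and 7 of the 23 were among them. Groups simulated without any change gave a mean of 0.42 calls in this comparison and a highest of 36 in 100 simulations.

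At 20 mM, 103 transcripts rose and 123 fell against the control. XM_010089470.1 fell from 66.6 ± 34.9 to 0.753 ± 0.227 FPKM (SD, n = 3), a log2 change of -5.14 ± 0.39 (SE, adjusted p = 0.000152). XM_010088470.1 fell from 79.1 ± 12.02 to 3.14 ± 1.70 FPKM, a log2 change of -4.35 ± 0.35 (adjusted p = 0.000152). XM_010107478.1 rose from 1.54 ± 1.62 to 36.0 ± 27.0 FPKM, a log2 change of 3.81 ± 0.80 (adjusted p = 0.0447). XM_010098200.1, listed in no control library, stood at 11.87, 64.15 and 23.8 FPKM (adjusted p = 0.0119).

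Abundant transcripts took part in both directions at 20 mM. A mean of at least 10 FPKM was reached by 67 of the 103 that rose and 84 of the 123 that fell, and a mean of at least 100 FPKM by 14 and 22. The median log2 change was 1.56 among those that rose and -1.92 among those that fell. Without the 7 rising transcripts that no control library listed and the 5 falling ones that no 20 mM library listed, the medians were 1.55 and -1.91. All 226 showed no overlap between treated and control libraries, as did 20.7% of all tested transcripts, where chance gives 10%. Median scaling gave 79 higher and 162 lower. At an unadjusted p under 0.05 the numbers were close to each other at 20 mM (2872) and 10 mM (2760), and the estimated share of changed transcripts was 32.1% and 28.5%. Other splits of the same libraries gave up to 1905 and 1828 such transcripts, so part of these shares may be spread between libraries. The count of 226 was 73 without 20 mM replicate 2, 75 without control replicate 1, 84 without 20 mM replicate 1, 114 without 5 mM replicate 2 and 137 without control replicate 3. The calls of XM_010089470.1 and XM_010088470.1 held in all 12 fits that left out 1 library. The adjusted p of XM_010098200.1 was 0.0535 without 20 mM replicate 2, within 0.00153 to 0.0535 over its alternatives. That of XM_010107478.1 lay between 0.0530 and 0.160 without any 1 of the control or 20 mM libraries or of 5 mM replicates 1 and 2, and was 0.0543 with a pseudocount of 0.1, 0.0635 without a filter and 0.0557 without the variance trend and with robust moderation, within 0.0285 to 0.160 over its alternatives.

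**Figure D1:**
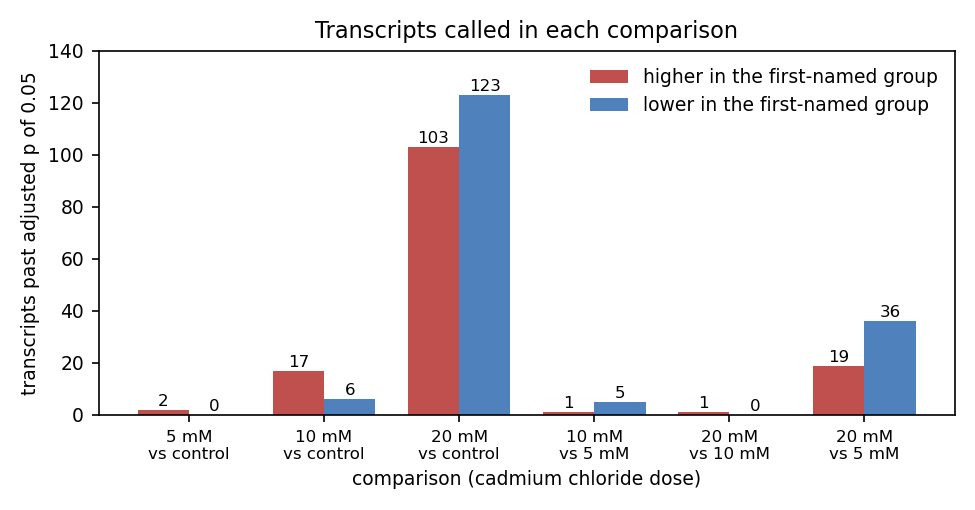
Number of transcripts with an adjusted p under 0.05 (vertical axis) in each of 6 comparisons between cadmium chloride doses (horizontal axis), with 3 libraries per group. Red bars count transcripts higher and blue bars those lower in the first-named group; the tallest pair is 20 mM against control, with 103 and 123.

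Transcripts called at 20 mM mostly lay between the control and 20 mM levels at the lower doses. The 103 that rose had median log2 changes of 0.49 at 5 mM, 0.88 at 10 mM and 1.56 at 20 mM, and 62 of them had group means in the order of the doses. The 123 that fell had medians of -0.45, -1.02 and -1.92, with 85 in the order of the doses. At 10 mM, 76 of the 103 and 91 of the 123 had an unadjusted p under 0.05, and at 5 mM 43 and 31 did. These transcripts were picked for their 20 mM change, which shares its controls with the other doses. Of the 226, 219 (96.9%) had the same sign at 10 mM and 201 (88.9%) at 5 mM, where simulated unchanged groups gave means of 85.9% and 86.8% and a highest of 100% at both doses.

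The calls overlapped between doses. In the same direction, 16 transcripts were called at both 10 and 20 mM, 11 higher and 5 lower, and 0 were called by limma in opposite directions. The 5 mM calls shared 2 transcripts with 20 mM and 1 with 10 mM. Simulated unchanged groups, whose lists of calls were nearly empty, shared 0 calls for each pair of doses. Lists of the observed sizes, made of the smallest p-values in those simulations, shared a mean of 7.03 transcripts for 10 and 20 mM, with as many as 16 in 13 of 100 simulations, 0.98 for 5 and 20 mM and 0.49 for 5 and 10 mM, with as many as observed in 40 and 36. Leaving the shared controls aside, independent lists of these sizes would share 0.140, 0.0116 and 0.00191 for 10 and 20 mM, 5 and 20 mM, and 5 and 10 mM. The covariance of log2 changes across transcripts was 0.191 between 10 and 20 mM (correlation 0.64), against a mean of 0.0843 and a highest of 0.201 in simulated unchanged groups, a difference of 0.107 from the mean. It was 0.131 against 0.0872 between 5 and 20 mM, a difference of 0.0442, and 0.110 against 0.0833 between 5 and 10 mM, a difference of 0.0270, where the highest simulated values were 0.203 and 0.161. All 3 observed covariances thus lay below the highest simulated value. The 3 control libraries are too few to split, so part of each excess may come from the shared controls. The 16 shared by 10 and 20 mM were 2 without control replicate 1, 5 mM replicate 2, 10 mM replicate 2 or 10 mM replicate 3, 3 without 5 mM replicate 3, 4 without control replicate 2 or 20 mM replicate 1, 6 without 20 mM replicate 3, 9 without 20 mM replicate 2 and 32 without 10 mM replicate 1, and with the replicate block they were 7. The 2 shared by 5 and 20 mM were 0 without control replicates 1 or 2, 5 mM replicates 1, 2 or 3 or 20 mM replicate 3, and 1 without control replicate 3, 10 mM replicate 1 or 20 mM replicate 2. The 1 shared by 5 and 10 mM was 0 without control replicates 1 or 2, 5 mM replicates 1, 2 or 3 or 20 mM replicate 3.

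**Figure D2:**
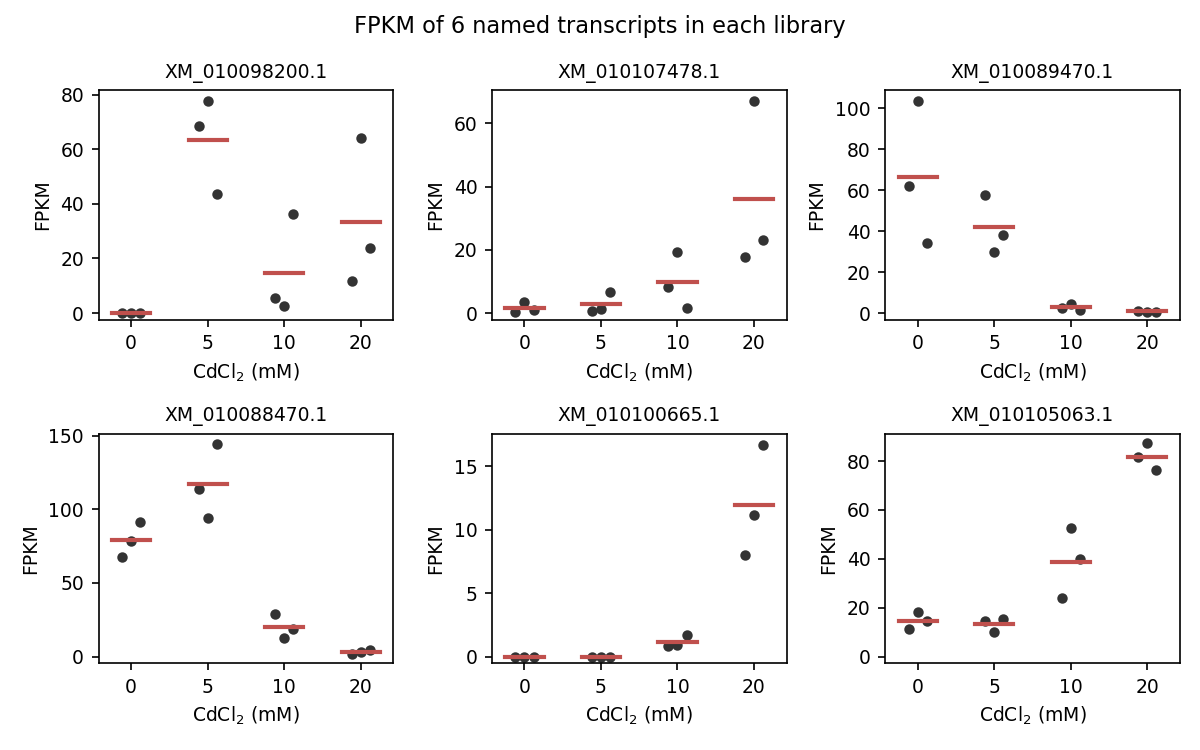
FPKM of 6 named transcripts (vertical axes) in each of the 12 libraries against the cadmium chloride dose in mM (horizontal axes), with 1 point per library and a red line at each group's mean. XM_010089470.1 and XM_010088470.1 were lowest at 20 mM, XM_010107478.1, XM_010100665.1 and XM_010105063.1 were highest there, and XM_010098200.1 was listed in no control library.

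Doses were also compared directly. Between 20 and 5 mM, 19 transcripts were higher and 36 lower at 20 mM. XM_010105063.1 rose from 13.4 ± 2.85 to 81.8 ± 5.47 FPKM (SD, n = 3), a log2 change of 2.54 ± 0.28 (SE, adjusted p = 0.00227). XM_010100665.1 was listed in no 5 mM library and stood at 7.99, 11.15 and 16.7 FPKM at 20 mM (adjusted p = 0.000186). XM_010088470.1 fell from 117 ± 25.0 to 3.14 ± 1.70 FPKM, a log2 change of -4.91 ± 0.35 (adjusted p = 0.000161). XM_010089470.1 fell from 41.8 ± 14.5 to 0.753 ± 0.227 FPKM, a log2 change of -4.56 ± 0.39 (adjusted p = 0.000344). The count of 55 was 18 without 5 mM replicate 3, 19 without 5 mM replicate 2, 23 without 20 mM replicate 1 and 26 without 20 mM replicate 2. The calls of the 4 named transcripts held in all 12 such fits.

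Between 10 and 5 mM, 1 transcript was higher and 5 were lower at 10 mM. XM_010100318.1 rose from 92.2 ± 22.9 to 383 ± 56.3 FPKM (SD, n = 3), a log2 change of 2.06 ± 0.27 (SE, adjusted p = 0.0279). XM_010089470.1 fell from 41.8 ± 14.5 to 2.85 ± 1.31 FPKM, a log2 change of -3.48 ± 0.39 (adjusted p = 0.0235). XM_010099860.1 fell from 647 ± 238 to 86.0 ± 20.4 FPKM, a log2 change of -2.86 ± 0.36 (adjusted p = 0.0279). Array weights gave 293 higher and 264 lower. After median scaling 0 were called higher by limma and 5 lower, with 1253 higher at an unadjusted p under 0.05 before that scaling. The count of 6 was 0 without any 1 of the 5 mM libraries or 10 mM replicate 3, 1 without control replicate 2 or 10 mM replicate 2, and 10 without control replicate 3. The call of XM_010089470.1 was lost without any 1 of the 5 mM libraries or 10 mM replicate 3 (adjusted p between 0.0694 and 0.160). Those of XM_010099860.1 and XM_010100318.1 were lost without control replicate 2 or any 1 of the 5 and 10 mM libraries, the second also without 20 mM replicate 1 (adjusted p between 0.0512 and 0.160 over both). Both were also lost without the variance trend and with robust moderation (0.0516 and 0.0629), and XM_010100318.1 after median scaling (0.0637). Fitted on the 5 and 10 mM libraries alone, each transcript named here lost its call.

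Between 20 and 10 mM, XM_010100665.1 was the only called transcript. It stood at 0.84, 0.89 and 1.7 FPKM at 10 mM and at 7.99, 11.15 and 16.7 FPKM at 20 mM, a log2 change of 2.56 ± 0.28 (SE, adjusted p = 0.0166). With limma 0 transcripts were called lower at 20 mM, against 971 lower and 763 higher at an unadjusted p under 0.05. A fit of only the 10 and 20 mM libraries also called 1 transcript, but not XM_010100665.1 (adjusted p = 0.222), whose call was lost with a pseudocount of 0.1 too (0.124, within 0.00721 to 0.222 over its alternatives). Among transcripts with a mean of at least 5 FPKM, 4 were called higher and 3 lower, and with array weights over all tested transcripts 57 and 42. The count of 1 was 0 without 5 mM replicate 3, 10 mM replicates 1 or 2 or 20 mM replicates 2 or 3, where the adjusted p of XM_010100665.1 lay between 0.0506 and 0.147, 2 without control replicate 2 or 5 mM replicates 1 or 2, and 3 without 20 mM replicate 1, 1 of them higher and 2 lower.

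Over the whole dose series, 94 transcripts rose and 152 fell with a linear trend in dose. A called slope does not show that the change was linear or graded, since the control and 20 mM libraries weigh most in it. Fewer transcripts were called when the trend was fitted to the treated groups alone, on fewer libraries. XM_010089470.1 changed by -5.55 ± 0.66 log2 units (SE) over 20 mM (adjusted p = 0.00155) and XM_010088470.1 by -4.90 ± 0.57 (adjusted p = 0.00123). The means of XM_010088470.1 were not in the order of the doses, at 79.1 FPKM in control, 117 at 5 mM, 20.0 at 10 mM and 3.14 at 20 mM. XM_010107478.1 rose by 3.98 ± 0.72 log2 units over 20 mM (adjusted p = 0.0154). XM_010100665.1, listed in no control or 5 mM library, also rose with dose (adjusted p = 0.000548). Of the 246 trending transcripts, 174 were called at 20 mM in the same direction and 72 were not called there. The count of 246 was 100 without 20 mM replicate 2, 107 without 20 mM replicate 1 and 122 without control replicate 1. The adjusted p of XM_010107478.1 was 0.0755 without 20 mM replicate 2, within 0.00699 to 0.0755 over its alternatives, and the other 3 calls held in all 12 fits.

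The test of any difference among the 4 groups called 115 transcripts, of which 93 were called at 20 mM against control and 17 at no dose. With the replicate block it called 60. XM_010089470.1, XM_010088470.1 and XM_010100665.1 each had an adjusted p of 0.000302 in this test without the block. XM_010107478.1, named at 20 mM and for the trend, was not called in it (adjusted p = 0.112). The count of 115 was 22 without 20 mM replicate 2, 25 without 20 mM replicate 1, 34 without 5 mM replicate 2, 38 without 5 mM replicate 3, 42 without 20 mM replicate 3, 49 without control replicate 1 or 10 mM replicate 3, 56 without control replicate 2 and 74 without control replicate 3.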

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

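The comparisons between doses, the splits of libraries and the alternatives with each library left out were planned, whereas the splits within replicate numbers, the count of transcripts beyond the lower doses and the tests of depth, of one library deciding the count and of the share of the top transcripts were chosen only after the result was seen.

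Tests of the difference between doses found that the response differed for 55 transcripts between 20 and 5 mM, for 6 between 10 and 5 mM and for 1 between 20 and 10 mM. These contrasts compared the doses directly, so the control cancels out of each difference. The order of the counts was not that of the unadjusted p-values, which were under 0.05 for 1719, 2046 and 1734 transcripts in the same comparisons, with estimated shares of changed transcripts of 13.8%, 22.7% and 20.0%. Other splits of the same libraries reached 1467, 1572 and 1638, so part of these shares may be spread between libraries. All 10 splits of the 6 libraries into 3 and 3 were fitted for each comparison, too few for a share under 0.05. The real split gave 55 calls between 20 and 5 mM and the highest other gave 1, so that 1 of 10 splits had as many. Between 10 and 5 mM the real split gave 6 and the highest other 1 (1 of 10), and between 20 and 10 mM the real split gave 1, as did 5 of the 10 splits in all.

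For the doses against control, where 10 splits are again too few for a share under 0.05, the real 20 mM split gave 226 calls and the highest other 0 (1 of 10 as large). At 5 mM the real split gave 2 and the highest other 1 (1 of 10). At 10 mM the real split gave 23 and the highest other 22 (1 of 10). That other split exchanged 10 mM replicate 1 with control replicate 3, and the 3 other splits that part all same-numbered pairs gave at most 0 calls by limma. At an unadjusted p under 0.05 those 3 splits gave 526 to 880 transcripts and the real one 2760. The 22-call split leaves control and 10 mM replicates 1 on the same side. Among 100 splits of all 12 libraries, the real one included, 1 gave as many as 246 trending transcripts, the highest other giving 11, and 1 gave as many as 115 in the test of any difference, the highest other giving 55. With the replicate block, and groups shuffled only within replicate numbers, 1 of 100 splits gave as many as 267 trending transcripts (highest other 42) and 1 as many as the 60 then called in the test of any difference (highest other 47). For these 2 results a chance arrangement of the libraries is argued against at a share under 0.05 in both forms, if the libraries are independent. The labels do not say whether the libraries of a group came from separate plants. A difference between plants could pass these splits as well.

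More transcripts were called at 20 mM (226) than at 5 mM (2). Over all tested transcripts, the direct contrast of 20 with 5 mM called 55. Among these were 15 of the 103 that rose and 30 of the 123 that fell at 20 mM against control. A single library as the source of the higher count is argued against, since the lowest 20 mM count was 73 with 1 library left out (20 mM replicate 2) and the highest 5 mM count was 2. Sequencing depth is argued against too: the mean worth of 1 read differed by -0.00637 between 20 and 5 mM, under the SD of 0.0260 at 5 mM. A graded effect of the dose stays open as a biological hypothesis, and so does a difference between groups in growth or harvest that the labels do not record.

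Replicate 1 at 10 mM stood apart from the other 2 of its group. Placed on the line from the control mean (0) to the 20 mM mean (1), over 103 transcripts called from control and 20 mM libraries alone, it lay at 0.347, against 0.577 and 0.640. Over these transcripts a mislabelled 5 mM or control library is argued against by this position, above the highest 5 mM library at 0.235 (SD of 0.0236 in its group). Of the 103, 45 lay beyond all control and 5 mM libraries towards 20 mM. Each 5 mM library, set against the others, had 27 or 28, and each control library, used in picking the transcripts, 5 to 8. Over all tested transcripts the values went the other way. On the first principal component replicate 1 lay at -21.1, within the range of -51.2 to -13.7 of the control and 5 mM libraries and away from the other 10 mM libraries (33.2 and 23.9). It correlated more with the 5 mM mean (0.955) and the control mean (0.953) than with its own group's mean (0.947). Only 6 of the 12 libraries were closest to the mean of their own group. For each library that mean was taken over the other 2 libraries of its group, fewer than for the other groups. This lowers the correlation with the own group by itself. A mislabelled library is thus not excluded. A few transcripts taking most of the signal is argued against by their share of 6.20%, inside the range of 5.43% to 7.30% over all libraries. A 10 mM root sample with a milder response stays open as a hypothesis, as no label records a difference.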

How the results depend on the processing

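The design, the naming rule and the alternatives were fixed before the data were examined, and no alternative was chosen after the result was seen. The gene lists and the camera test with an estimated correlation were not run, as the identifiers carry no names. Among 434 alternative fits of 21 named results, 338 kept the call, 96 lost it and 0 turned direction in any limma fit. The counts at 20 mM, between 20 and 5 mM and for the trend stayed within 1.5 times under pseudocount, filter, scaling, variance-trend and fold settings. Absolute depth is unknown, so what it limits was not measured.

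With a pseudocount of 0.1, 36 transcripts were called at 10 mM, 0 between 20 and 10 mM (1734 at an unadjusted p under 0.05 with a pseudocount of 1), and 3 were shared by 5 and 10 mM. Without a filter the counts were 1 at 5 mM, 6 at 10 mM, 3 between 20 and 10 mM and 68 among the 4 groups, with 5 shared by 10 and 20 mM and 1 by 5 and 20 mM. With a mean of at least 5 FPKM they were 0 at 5 mM (XM_010110569.1 lies under that mean, and XM_010098200.1 had an adjusted p of 0.0740, within 0.000583 to 0.301 over its alternatives), 46 at 10 mM and 7 between 20 and 10 mM (4 higher and 3 lower), with 0 shared by 5 and 10 mM or 5 and 20 mM. Median scaling and quantile normalization each gave 1 at 5 mM and 1 shared by 5 and 20 mM. They kept 192 and 205 of the 226 calls at 20 mM. Without the variance trend and with robust moderation, changed together, the counts were 1 at 5 mM, 4 at 10 mM, 2 between 10 and 5 mM and 76 among the 4 groups, with 4 shared by 10 and 20 mM and 1 by 5 and 20 mM.

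Array weights raised the counts to 190 at 10 mM, 443 at 20 mM, 557 between 10 and 5 mM, 99 between 20 and 10 mM, 672 between 20 and 5 mM, 943 among the 4 groups and 419 for the trend, with 2 shared by 5 and 10 mM and 87 by 10 and 20 mM. With only the 2 groups compared, a fit on fewer libraries, the counts were 4 at 5 mM (1 higher and 3 lower), 1 at 10 mM, 103 at 20 mM, 1 between 10 and 5 mM and 95 between 20 and 5 mM. The trend over treated groups alone, also on fewer libraries, gave 37. Apart from those fits, the cause was not tested.

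With the replicate block the counts were 0 at 5 mM (1624 at an unadjusted p under 0.05 without it), 8 at 10 mM, 2 between 20 and 10 mM and 60 among the 4 groups, with 0 shared by 5 and 10 mM, 7 by 10 and 20 mM and 0 by 5 and 20 mM. It moved no other count by over 1.5 times (239 at 20 mM, 267 for the trend). Over all 18 same-numbered pairs the correlation of deviations ran from -0.187 to 0.268, with 5 above 0.1, and 8 of the 12 libraries were closest to 1 of their own number, as a hint from the data.

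Leaving out 1 library gave 0 to 2 calls at 5 mM, 2 to 43 at 10 mM, 73 to 321 at 20 mM, 0 to 10 between 10 and 5 mM, 0 to 3 between 20 and 10 mM, 18 to 80 between 20 and 5 mM, 22 to 146 among the 4 groups and 100 to 305 for the trend. The calls shared ran from 0 to 1 for 5 and 10 mM, 2 to 32 for 10 and 20 mM and 0 to 2 for 5 and 20 mM.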

Other observations

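The tests of consecutive identifiers against chance order and of unlisted transcripts against chance were chosen only after the result was seen; the tests of abundance, of shared reads and of a graded response were written before.

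A small set of transcripts was called at 10 mM but not at 20 mM. It held 6 that rose and 1 that fell, and all 7 had a larger change at 10 mM than at 20 mM. For 6 of them the unadjusted p between 20 and 10 mM was under 0.05, and 0 passed the adjusted threshold of limma. They were picked by their call at 10 mM, which favours a larger value there.

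Another set was absent from the controls. Of the tested transcripts, 4 were listed in all 9 treated libraries, with a mean of at least 1 FPKM there, and in no control library: XM_010089104.1, XM_010098200.1, XM_010098988.1 and XM_010110569.1, named after their values were seen. XM_010098200.1 ranged from 2.43 to 36.44 FPKM at 10 mM, and XM_010110569.1 lay between 2.64 and 5.98 FPKM in all 9. Of the 220 sets of 3 libraries, 3 had at least as many such transcripts. The set of controls was among these, and so was the highest other set, with 5. These 3 sets are under the bar of 5% of the sets, but the test was made on the transcripts that prompted it. A chance pattern of unlisted transcripts therefore cannot be told apart from an effect of cadmium. The worth of 1 read was also higher in the control libraries (1.04 to 1.06) than in any treated library (at most 1.01), so the controls were the least deep. That limits low values such as those of XM_010089104.1, at 0.37 to 0.39 FPKM at 5 mM. Of 6603 transcripts with a median of at least 20 FPKM where listed, 6 were unlisted in 1 or more libraries, XM_010098200.1 among them. Among transcripts left out for low values, 50 were listed in all 3 20 mM libraries and no control, and 59 the other way round. Of the 20 splits of these 6 libraries, counted in both directions, 3 had at least as many as 50. The real grouping is among these in both of its directions, and so few splits cannot give a share under 0.05. An effect of cadmium cannot be told apart from chance in these counts.

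Position on the 20 mM response was measured for each library over the 103 transcripts (46 higher and 57 lower) called from control and 20 mM libraries alone. The 5 mM libraries lay at 0.235, 0.220 and 0.188 (mean 0.214 ± 0.0236 SD, n = 3) and the 10 mM libraries at 0.347, 0.577 and 0.640 (mean 0.521 ± 0.154). The difference of 0.307 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. A graded response from 5 to 10 to 20 mM is a hypothesis that was tested in these transcripts through the share that differed between 10 and 5 mM in the direction of the 20 mM call. That share was 84.5% (87 of 103, exact Clopper-Pearson 95% interval 76.0% to 90.9%, which treats transcripts as independent), but 1 of the other splits of the 5 and 10 mM libraries, which exchanges only 10 mM replicate 1 and 5 mM replicate 2, gave 88.3%. The difference, 91 against 87 transcripts, lies inside that interval, so a graded response and a chance arrangement of these libraries cannot be told apart here.

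Transcripts with consecutive accession numbers had correlated statistics at 20 mM against control. Over 12460 such pairs the correlation of moderated t statistics from limma was 0.138. Over tested transcripts in accession order it was 0.0485 between those 2 places apart, -0.0122 at 10 places and -0.00155 at 50. Chance order of the identifiers is argued against by a one-sided permutation p of 0.0001, the smallest that 10000 shuffles can give, the highest shuffle reaching 0.0314. Similar abundance of neighbours is argued against as the whole cause, since the correlation was 0.136 after a smooth trend on abundance was removed. Reads shared between near-identical neighbours cannot be told apart from co-regulation of adjacent genes, because no sequences were used. Whether consecutive numbers mark adjacent genes was not checked. Neighbours also deviated together within groups, where the dose is the same (mean correlation 0.101, from 0.0614 to 0.124 over the libraries). The shuffles break up that shared spread too, so the correlation of 0.138 need not reflect a response to cadmium.

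Both members were called at 20 mM in 9 of these pairs, 8 of them in the same direction, where 2.01 were expected by chance (one-sided permutation p = 0.0003, 10000 shuffles). The shuffles treat neighbours as independent, although they deviated together within groups. The excess of pairs therefore need not come from cadmium.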
